A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

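Total RNA of 3 Schizosaccharomyces pombe cultures was measured on 3 Affymetrix arrays, 1 each for wild type, the eca39 deletion strain and the adapted deletion strain. Per the labels' protocols, RNA was extracted with acid phenol and cleaned on RNeasy columns, and labelled with biotin by the Affymetrix 3' IVT Express kit, which reads transcripts from their 3' ends. Nothing in the labels says that more than 1 culture was made per group.

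The deposited values are on the log2 scale, as produced by the authors with RMA in the affy package, per the submitters' processing notes. No versions were given there. RMA corrects the background on each array, sets all arrays to the same distribution by quantile normalization, and summarizes the probes of a probe set by median polish. The log base was not written out and was taken as 2, from RMA's usual output and the range of 2.99 to 15.17. Quantile normalization assumes that arrays share 1 distribution, so a shift of most transcripts in 1 culture would not be seen. Median polish can return identical values on different arrays, which gives differences of exactly 0. Which probe sets were left out before the table was made, and the genome build of the array, are not given in the sources used here.

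Names came from the platform annotation, which can be old. Of 4999 probe sets, 2917 had 1 gene name, 20 had several and 2062 had none, and no name was taken from a probe set with several. The gene number of 2914 probe sets matched a gene table of assembly ASM294v3, and 109 names were updated through it. That table was used for names and for the order of genes only, and none of its positions are given. Probe sets of 1 gene were averaged on the log2 scale, which left 2899 named genes and 2082 unnamed probe sets, 4981 features in all. For 14 genes with several probe sets, the median gap between their differences from wild type was 0.19 in the deletion and 0.16 in the adapted culture, and the largest gap was 4.14. No control probe sets were present, and 69 probe sets carried the suffixes _s_at or _x_at, which mark probes that may hybridize to several transcripts. Probe sets of near-identical genes, such as the mfm, wtf and ribosomal protein genes, may read each other's transcripts.

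Each group had 1 array, so differences between log2 values were described by a size rule without a test. A feature rose or fell when its log2 values differed by at least 1 and the higher value reached the 30th percentile of the table, 9.82. This limit was reached by 68.9%, 70.2% and 71.0% of probe sets on the wild-type, deletion and adapted arrays. The standard deviation of all differences was 0.413 between the deletion culture and wild type, 0.374 between the adapted culture and wild type, and 0.245 between both mutant cultures. Dim features read lower on the wild-type array, since among the 1661 dimmest the median difference was 0.08 in the deletion and 0.11 in the adapted culture. Pearson correlations across probe sets were 0.982, 0.985 and 0.993 for these pairs.

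The size rule, 28 gene lists and the genes to be named were fixed before the data were examined. For each comparison these were the 12 largest differences in each direction among named genes that passed the size rule, all measured branched-chain synthesis genes, eca39 and its neighbours, and up to 4 members of each other list by absolute difference. Lists with at least 5 measured members, 26 of 28, received a percentile for their median among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists cover the synthesis of branched-chain, other, and glutamate-family amino acids, permeases, nitrogen starvation, purines, sulfate, core and oxidative stress, chaperones, iron, copper and zinc, phosphate and thiamine, hexoses, glycolysis, respiration, ribosomal proteins, ribosome biogenesis, M-type and P-type mating, meiosis, autophagy, adhesins, cell separation, histones, G1/S, sterols, and wtf genes. Some genes belong to several lists, such as isp6, gst2 and hsp16, and cyp1, a cyclophilin gene, stayed in the sterol list by oversight.

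Both mutant cultures share the wild-type array, so unchanged groups that shared a simulated control array were drawn 100 times. Their noise was taken from the differences between the mutant arrays, which also hold real effects. The size rule was tested on simulated data for the deletion culture against wild type over 4981 features with 200 planted changes. It recovered 2% of 50 features changed 1.5-fold, 48% of those changed 2-fold and 100% of those changed 3-fold or 4-fold. Of 4781 unchanged features it called 1. The changes were planted only in features whose mean reached the brightness limit, and the noise again came from the differences between the mutant arrays. Their standard deviation was 0.245, against 0.413 between the deletion culture and wild type. The rate of false calls in that real comparison was therefore not estimated. Of 200 random lists without an effect, 3% fell outside the 2.5th to 97.5th percentiles. These were random genes in independent noise, so that rate does not cover lists whose members vary together or read each other's transcripts.

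Alternatives were no brightness limit or one at the 50th percentile, thresholds of 1.5-fold and 3-fold, differences centred on their median, an intensity trend removed by loess (span 0.4, 3 iterations), repeated quantile normalization, the brightest probe set per gene, and leaving out _s_at and _x_at probe sets. A limit at the 10th percentile, and lists and correlations without eca39 or without mei2 and ste11, were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.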

Results

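Gene expression was measured in 3 cultures of the fission yeast Schizosaccharomyces pombe, with 1 Affymetrix array for each. The wild-type culture was a prototrophic strain (SpHT219, h-). The deletion culture came from a strain of the same mating type (SpHT257-1) in which the kanMX4 cassette replaced eca39, the gene of the branched-chain amino acid aminotransferase. The adapted culture was the same deletion strain after growth close to wild-type cells on a minimal plate (EMM2-N) that held 15 mM glutamate and 2 mM isoleucine, leucine and valine. Wild type and the unadapted deletion strain came from plates of rich medium (YE) instead, so adaptation and plate history could not be told apart. All cultures then grew in liquid YE with 2 mM isoleucine, leucine and valine from an optical density of about 0.1 to about 1. The design compared the transcriptome of the deletion strain with wild type, before and after adaptation, and the adapted with the unadapted deletion culture.

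The table held 4999 probe sets, given as log2 expression values, with medians of 10.64 in wild type, 10.69 in the deletion culture and 10.69 in the adapted culture. After probe sets of 1 gene were averaged, 4981 features remained, of which 2899 were named genes and 2082 were probe sets without a single name. A feature was said to rise or fall if its values differed at least 2-fold and the brighter of the 2 arrays reached the 30th percentile of all values, 9.82. With 1 array per group no difference had a replicate check and no p-value was computed, and the number of arrays limits the precision of every value. Percentiles given for gene lists place a list's median difference among those of 10000 random lists matched on size and mean expression, as a description of these arrays.

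The deleted gene was measured before all others. The eca39 probe set (SPBC428.02C) read 14.60 in wild type, at the 97.4th percentile of that array, and 6.12 in the deletion culture, at the 4.2th percentile, a signal at least 358-fold lower. In the adapted culture it read 6.37, at the 4.5th percentile and at least 302-fold below wild type. Both readings lay near the bottom of the scale, so these folds are lower bounds. Counted whole as eca39 signal, the adapted reading would be 0.332% of that of wild type. The nearest measured protein-coding genes on either side, by gene order in assembly ASM294v3, did not pass the size rule. The nucleoporin gene nup107 read 11.46, 11.40 and 11.42 in wild type, the deletion and the adapted culture, and the phosphatase gene pho4 read 12.27, 12.11 and 12.14.

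The deletion culture expressed higher levels of several genes of nitrogen and amino acid metabolism than wild type, while few features were lower. In total 82 features rose and 3 fell, out of 3569 that reached the brightness limit, and 27 of those that rose and 2 of those that fell were named genes. The largest named differences were those of aes1 (11.1-fold, from 10.61 to 14.08), mug14, a gene named for its induction in meiosis (10.3-fold, from 7.33 to 10.70), and the uracil-induced gene urg1 (10.2-fold, from 10.03 to 13.38). They were followed by aca1 (9.02-fold), gdh2, which encodes the NAD-dependent glutamate dehydrogenase (7.64-fold, from 11.19 to 14.12), and urg2 (5.73-fold). The wild-type reading of mug14 lay below the 10th percentile of the table, 7.92, so its fold and rank are uncertain. The pantothenate transporter gene liz1 rose 3.75-fold, the amino acid permease gene per1 3.62-fold, mmf2 3.51-fold, the cyclin gene pas1 3.28-fold, the ubiquitin protease gene ubp11 3.00-fold and the glutathione transferase gene gst2 2.81-fold.

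Genes of amino acid synthesis stood above wild type as a group. Of the 5 measured genes for branched-chain amino acid synthesis other than eca39, none passed the size rule, but all 5 lay above 0, with log2 differences of 0.64 for leu3, 0.48 for ilv1, 0.41 for leu2, 0.27 for leu1 and 0.05 for ilv5. The median of that list was 0.34 with eca39 (99.55th percentile) and 0.41 without it (99.44th percentile). Among 30 genes for the synthesis of other amino acids, 3 rose, 25 lay above 0 and the median was 0.40, above the medians of all random lists. The 3 were the arginine genes arg3 (2.39-fold) and arg5 (2.04-fold) and the histidine gene his4 (2.33-fold), and arg12 stood at a difference of 0.86. In the list for glutamate, glutamine and asparagine synthesis, only gdh2 rose, and as the gene of the NAD-dependent enzyme it need not act in synthesis. In the same list asn1 (0.62), gdh1 (0.51) and glt1 (0.31) lay above 0, while gln1 was at -0.06, and the median was 0.51 (99.86th percentile). Of 8 amino acid and peptide permeases measured out of 23 listed, per1 rose and the median was 0.50 (99.98th percentile). Isp5, cat1 and aat1 had differences of 0.74, 0.65 and 0.60, the first of them below the brightness limit on both arrays.

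Genes known to respond to nitrogen starvation had a median difference of 0.32 (99.95th percentile), with 10 of 13 above 0. Of these, isp6, the gene of a vacuolar protease, rose 2.05-fold, and mei2, amt3 and amt1 had differences of 0.95, 0.81 and 0.76. Autophagy and vacuolar protease genes were above 0 for 21 of 22 members, with a median of 0.26 (99.86th percentile) and isp6 as the only member that rose. Only 10 of the 22 reached the brightness limit on any array, and the median became 0.17 after the intensity trend was removed and 0.11 under repeated quantile normalization. Of 13 genes in the list of oxidative stress targets of the transcription factor Pap1, gst2 and the sulfiredoxin gene srx1 (2.24-fold) rose and the median was 0.16 (99.9th percentile). The 20 core stress response genes had a median of 0.15 (99.84th percentile), but their members went apart. Of these gst2 and sro1 (2.02-fold) rose, and hsp16, which encodes a small heat shock protein, fell 3.07-fold, from 11.86 to 10.24. The hexose transporter gene ght5 rose 2.11-fold, in a list of 18 glucose-related genes with a median of 0.21 (97.48th percentile). Only 8 of these 18 reached the brightness limit on any array. The alcohol dehydrogenase gene adh4 rose 2.15-fold, and the 6 copper and zinc genes had a median of 0.09 (91.5th percentile). Citrate synthase (cit1, 2.05-fold) was the only one of 29 genes of the tricarboxylic acid cycle and respiration to rise, and the list's median was -0.0072. Iron acquisition genes had a median of 0.23 (98.93rd percentile) over 9 members, of which fip1, fio1 and str3 lay at 0.77, 0.62 and 0.61 and none passed the size rule.

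Other groups had medians below wild type without any member that fell, hsp16 aside. The 7 G1/S genes had a median of -0.42, below all random lists, with cdt1 at -0.73, cig2 at -0.65, cdc22 at -0.62 and cdc18 at -0.42, and suc22 alone above 0, at 0.04. Cell separation genes had a median of -0.36 (0.01 percentile), with adg3 at -0.61 and adg1 at -0.56, and 9 of 10 histone genes lay below 0 with a median of -0.14 (0.04 percentile). The 13 chaperone genes, hsp16 included, had a median of -0.17 (0.05 percentile), and ssa1 read -0.64 below wild type on the log2 scale. Ribosome biogenesis genes were below 0 for 23 of 26 members, with a median of -0.20 (0.02 percentile) and gar2 and rrs1 at -0.47 and -0.43. The 112 cytosolic ribosomal protein genes had a median of -0.010 (11.2th percentile), which turned to 0.010 after the intensity trend between arrays was removed. Most of them read near the top of the scale, which ended at 15.12 to 15.17 on these arrays, so changes may be understated. Before that removal 70 lay below and 11 above 0, with rpl1603 at -0.62, rpl102 at -0.45 and rpl4101 at 0.22. The same limit applies in the other comparisons, to most glycolysis genes and to ilv5 (14.66 in wild type).

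The remaining lists gave no member that rose or fell. Purine synthesis had a median of -0.0037 (76.1st percentile), with ade7 at 0.81, and glycolysis one of -0.0073 (46.5th percentile). Both medians, and that of the tricarboxylic acid cycle list, were above 0 after removal of the intensity trend, at 0.049, 0.010 and 0.045. The median was 0 for sulfate assimilation (77.5th percentile), -0.018 for phosphate and thiamine genes (21.0th percentile) and -0.12 for sterol synthesis and low-oxygen genes (5.05th percentile). The 6 mating genes of M-type cells, the mating type of these strains, had a median of 0.22 (82.5th percentile). The 3 measured P-type genes had one of -0.058 and 4 adhesin genes one of 0.12, both too few for a percentile. Meiosis and sporulation genes (median 0.30, 94.1st percentile) and the wtf genes (median 0.47, 99.64th percentile) were dim, with 2 of 21 and 1 of 16 members at the brightness limit on any array. Repeated quantile normalization moved the medians of these lists to -0.051 and 0.12. The count of 82 features that rose became 148 without the brightness limit, 197 at a 1.5-fold threshold and 36 at a 3-fold threshold, and the 3 that fell became 22 at 1.5-fold. Of the 12 named genes with the largest rises, mmf2 no longer passed with a brightness limit at the 50th percentile.

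**Figure D1:**
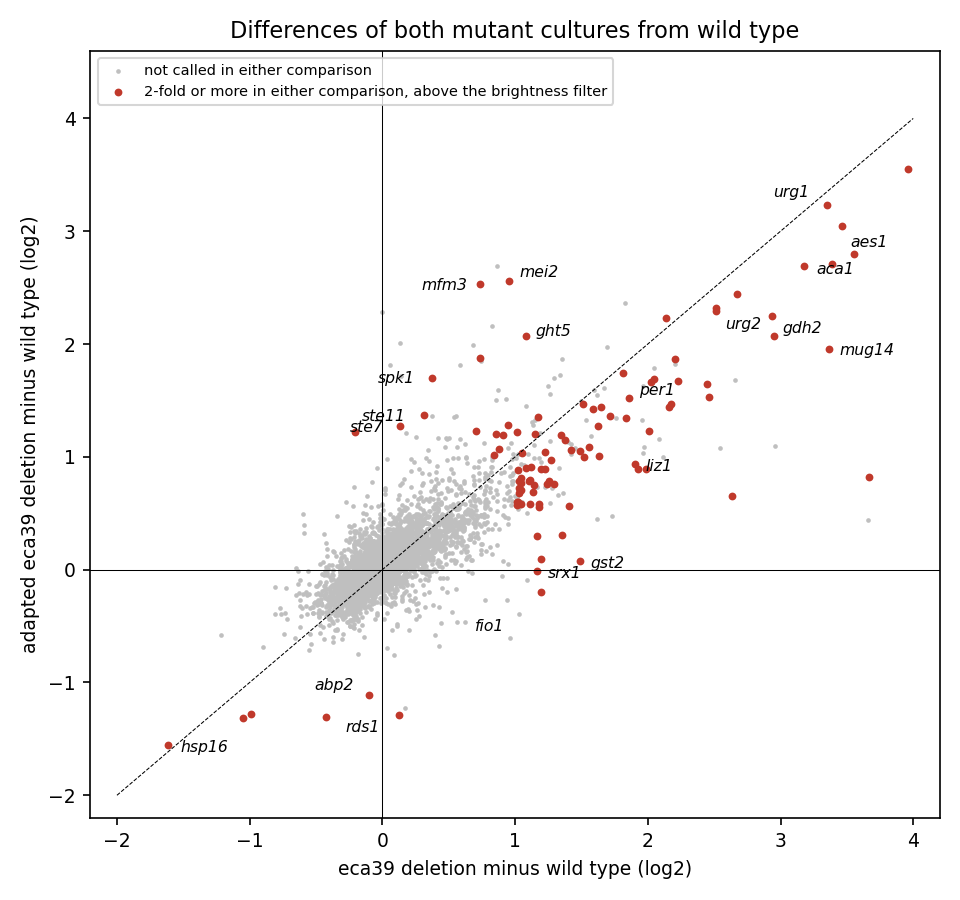
Log2 difference of each feature from wild type in the deletion culture (x axis) and in the adapted culture (y axis), 1 array per culture, with features that rose or fell in either comparison in red and the line of equal differences dashed; eca39, at -8.48 and -8.24, lies outside the axes. Most red points lie above 0 on both axes, and mei2 and mfm3 lie above the dashed line.

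The adapted culture shared most of the largest differences from wild type and in addition expressed higher levels of mei2, mfm3, spk1, ste11 and ste7. In total 53 features rose and 8 fell, out of 3588 that reached the brightness limit, and 17 and 4 of them were named genes. The largest among named genes were again urg1 (9.40-fold), aes1 (8.26-fold) and aca1 (6.46-fold), with urg2 at 4.91-fold and gdh2 at 4.74-fold. Between them stood mei2, the gene of an RNA-binding protein that governs entry into meiosis (5.89-fold, from 9.16 to 11.72), and mfm3, a gene of the M-factor pheromone precursor (5.80-fold, from 7.47 to 10.01). The wild-type reading of mfm3 also lay below the 10th percentile of the table, 7.92, so its fold is uncertain. The gene ght5 rose 4.22-fold, mmf2 3.35-fold, the pheromone-pathway kinase gene spk1 3.24-fold, per1 2.88-fold and ubp11 2.68-fold. The mating transcription factor gene ste11 rose 2.59-fold, pas1 2.56-fold, ste7 2.42-fold and his4 2.06-fold. Besides eca39, hsp16 fell 2.94-fold, rds1 2.45-fold and abp2 2.15-fold. A probe set named pho1 on the platform rose 2.02-fold, but its gene number now belongs to a non-coding RNA at that locus, so which transcript it read stays uncertain.

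The 6 M-type mating genes had a median difference of 1.10, above all random lists, with 5 of 6 above 0. Of these mfm3 rose, mfm1 (2.69) and mam2 (1.21) exceeded 2-fold below the brightness limit, and mfm2 (0.98), mam1 (0.63) and sxa2 (-0.015) did not reach 2-fold. The mfm genes encode near-identical pheromone precursors, so their probe sets may not separate them. The 3 measured P-type genes had a median of -0.13. Nitrogen starvation genes had a median of 0.42, above all random lists, 12 of 13 were above 0, and mei2 and ste11 rose. Without these genes, which also act in mating, that median was 0.41 (99.98th percentile). The permeases had a median of 0.48, above all random lists, and isp5, at 1.85, exceeded 2-fold below the brightness limit. Branched-chain synthesis genes had a median of 0.23 (99.04th percentile), with leu3 at 0.41 and leu2 at 0.32. The other amino acid synthesis genes had one of 0.26, above all random lists, with his4 as the only member that rose and arg3 at 0.79. The median was 0.36 for glutamate, glutamine and asparagine synthesis (99.66th percentile) and 0.32 for autophagy and vacuolar proteases (99.96th percentile), where none of 22 rose. The last of these became 0.21 after the intensity trend was removed and 0.13 under repeated quantile normalization.

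Several lists that stood apart in the deletion culture had medians nearer to wild type in the adapted culture. The Pap1 list had a median of -0.0041 (27.7th percentile), with gst2 at 0.07 and srx1 at -0.016. The G1/S genes had one of -0.029 (10.5th percentile) and cell separation genes one of -0.11 (4.77th percentile). Histones had one of 0.032 (92.3rd percentile), which became -0.0067 under repeated quantile normalization. Chaperones had a median of -0.031 (4.99th percentile), iron acquisition genes one of 0.091 (77.4th percentile) and core stress genes one of 0.093 (95.3rd percentile), the last of which became -0.024 under repeated quantile normalization. Single members were not all nearer to wild type. Iron acquisition genes ran from -0.47 to 0.41, with 5 above and 4 below 0, and in the core stress list hsp16 and rds1 fell. Ribosome biogenesis genes kept a median of -0.18, below all random lists, with 25 of 26 below 0. For the remaining lists the median was 0.20 in the hexose list (94.0th percentile), 0.078 in the copper and zinc list (76.2nd percentile), -0.013 in the phosphate and thiamine list (9.92th percentile) and -0.063 in the sterol list (5.26th percentile). It was 0.048 for the tricarboxylic acid cycle and respiration (92.0th percentile), -0.0044 for purines (39.7th percentile), -0.0023 for sulfate assimilation (34.8th percentile), 0 for glycolysis (43.5th percentile) and 0 for ribosomal proteins (48.6th percentile). After the intensity trend was removed, the ribosomal protein median was -0.0032 (1.125th percentile), with 24 members above and 88 below 0. Adhesin genes had a median of 0.056 over 4 members. The dim meiosis list had a median of 0.43 (97.9th percentile), which became 0.030 under repeated quantile normalization, and the wtf list had one of 0.51 (99.65th percentile), which became 0.27. The count of 53 features that rose became 124 without the brightness limit, 87 with a limit at the 10th percentile that was chosen after the data were seen, 130 at 1.5-fold and 23 at 3-fold. The 8 that fell became 15 at 1.5-fold and 2 at 3-fold, and mfm3, mmf2 and spk1 no longer passed with the limit at the 50th percentile.

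**Figure D2:**
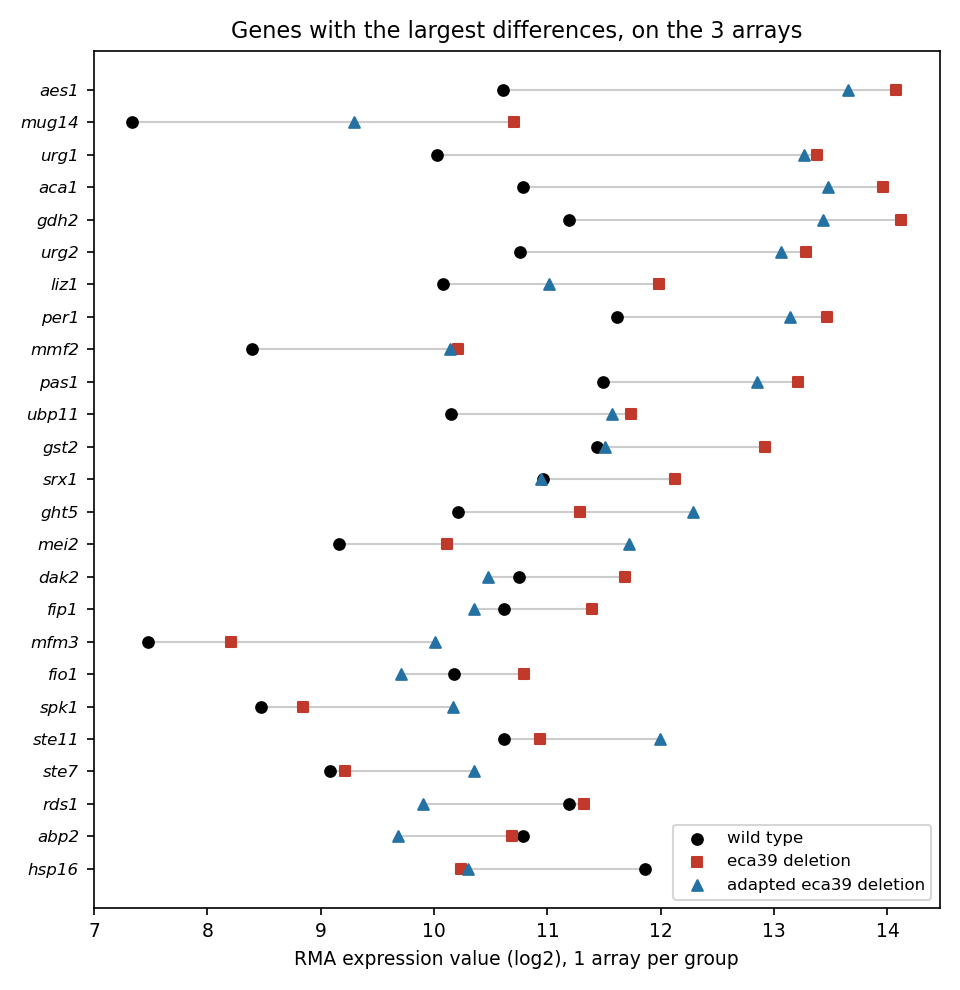
Log2 expression values of the named genes with the largest differences, with 1 point per array, for wild type (circles), the deletion culture (squares) and the adapted culture (triangles). For aes1, urg1, aca1 and gdh2 both mutant cultures lie far to the right of wild type, for mei2, mfm3, spk1 and ste11 the adapted culture lies farthest to the right, and for gst2 and srx1 it lies near wild type.

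The adapted culture differed from the unadapted deletion culture by higher levels of the same 5 genes, while 2 genes of oxidative stress and 2 of iron uptake were lower. In total 7 features rose and 17 fell, out of 3609 that reached the brightness limit, and 5 and 8 of them were named genes. The 5 that rose were mfm3 (3.49-fold), mei2 (3.04-fold), spk1 (a log2 difference of 1.32), ste7 (2.21-fold) and ste11 (2.08-fold). With the brightness limit at the 50th percentile mfm3, spk1 and ste7 no longer passed, and mei2 and ste11 did. The 8 that fell were rds1 (2.67-fold), gst2 (2.67-fold), mug14 (2.66-fold), the dihydroxyacetone kinase gene dak2 (2.32-fold), srx1 (2.27-fold), the ferroxidase gene fio1 (2.12-fold), the iron permease gene fip1 (2.05-fold) and abp2 (from 10.68 to 9.68). The gene ght5 lay just under the threshold, with a log2 difference of 0.997, and eca39 differed by 0.25.

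The M-type list had a median of 0.99 between the cultures, above all random lists, with mfm3 as the only member of 6 that rose and mfm1, mfm3, mam2 and mfm2 at 1.83, 1.80, 1.03 and 0.94. The nitrogen starvation list had a median of 0.05 (80.02nd percentile), in which mei2 and ste11 rose and isp5 stood at 1.11 below the brightness limit, while amt1 (-0.35) and isp6 (-0.30) were lower. Of the 13 Pap1 genes, gst2 and srx1 fell, 11 lay below 0 and the median was -0.14 (0.02 percentile). Iron acquisition genes had a median of -0.14 (0.475 percentile), with 2 that fell and 7 of 9 below 0. The G1/S genes were above 0 for 7 of 7 members, with a median of 0.39 (99.99th percentile) and cig2 at 0.66. Cell separation genes were above 0 for 6 of 6 with a median of 0.26 (99.9th percentile), and histones had a median of 0.15, above all random lists. Chaperones had a median of 0.08 (98.4th percentile), with ssa1 at 0.51. Amino acid synthesis lay lower than in the unadapted culture. Of 30 other amino acid genes 25 were below 0, with a median of -0.12, below all random lists, and all 5 glutamate, glutamine and asparagine genes were below 0 with a median of -0.16 (0.17 percentile). The largest difference among these 5 was that of gdh2, at -0.69, which need not act in synthesis. The branched-chain list had a median of -0.064 with eca39 (3.84th percentile) and -0.086 without it (2.75th percentile).

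The other lists lay close to 0 between the 2 mutant cultures. The median was 0.020 for permeases (47.2nd percentile), -0.035 for purines (2.97th percentile), -0.0023 for sulfate assimilation (13.3rd percentile), 0.047 for core stress genes (84.3rd percentile) and 0.047 for the hexose list (84.6th percentile). In the core stress list rds1 and gst2 fell, and in the hexose list dak2 fell. It was -0.027 for copper and zinc (13.4th percentile), although the copper transporter gene ctr4 stood at 0.95, and 0.043 for phosphate and thiamine genes (76.9th percentile). It was 0.019 for glycolysis (69.3rd percentile), 0.068 for the tricarboxylic acid cycle and respiration (91.3rd percentile), 0.0070 for ribosomal proteins (28th percentile), 0.00037 for ribosome biogenesis (24.01st percentile), 0.089 for sterol genes (92.0th percentile) and 0.011 for autophagy (62.1st percentile). It was 0 for meiosis genes (45.1st percentile) and 0.013 for wtf genes (79.9th percentile), while P-type genes had a median of 0.065 and adhesins one of -0.050. The medians of the permease, ribosomal protein, ribosome biogenesis, autophagy and wtf lists changed sign under at least 1 of 3 other scalings. The 7 features that rose became 18 without the brightness limit, 15 with the limit at the 10th percentile, 4 with it at the 50th, 24 at 1.5-fold and 2 at 3-fold. The 17 that fell became 28 without the limit, 55 at 1.5-fold and 3 at 3-fold.

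**Figure D3:**
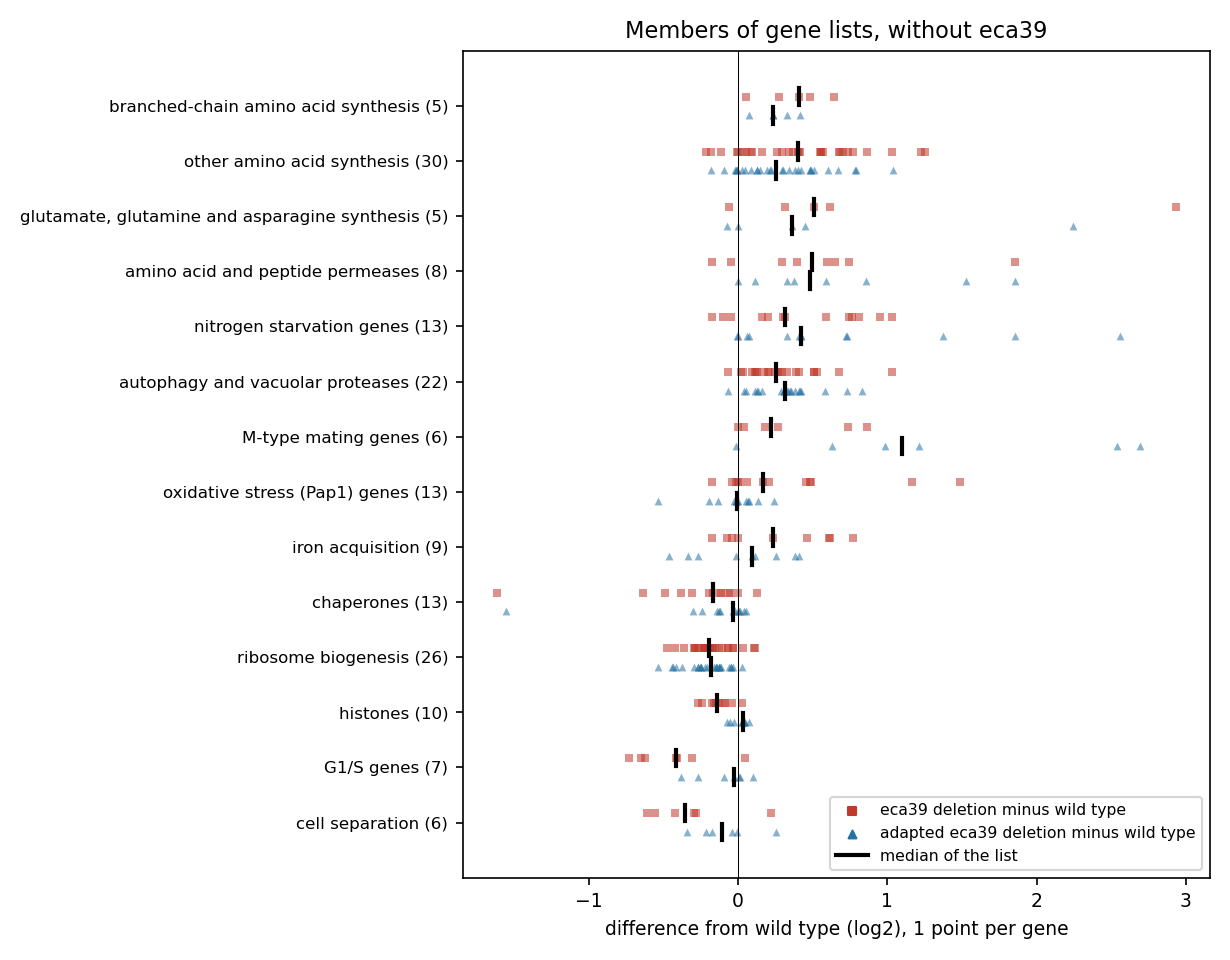
Log2 difference from wild type of each member of 14 gene lists, eca39 left out, in the deletion culture (squares) and the adapted culture (triangles), with bars at the list medians and the number of genes in brackets. M-type mating genes reach a median of 1.10 in the adapted culture against 0.22 in the deletion culture, and G1/S genes lie at -0.42 in the deletion culture against -0.029 in the adapted culture.

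The differences of both mutant cultures from wild type were compared across all features. Their Pearson correlation was 0.810 with eca39 and 0.791 without it, across features that are not independent replicates. Unchanged groups simulated with a shared, simulated control array gave 0.498, a value that follows from giving all arrays the same noise. The covariance was 0.111 without eca39 against 0.0298 in the simulation, a difference of 0.0811. This difference largely restates that the standard deviations from wild type, 0.413 and 0.374, exceeded the 0.245 between the mutant cultures. Of 3522 features that reached the brightness limit in both comparisons, 39 rose in both and 3 fell in both. Independent lists of these sizes would share 1.23 and 0.0068, but that count ignores the shared wild-type array. The simulated unchanged groups shared 0 that rose, a count nearly fixed by their low noise. The simulated control array had the same noise as the simulated mutant arrays. A wild-type culture that differed by itself would raise the correlation, the covariance and the shared counts. As that single array cannot be split, part or all of the excess may come from the shared control. No feature passed the size rule in opposite directions. Of the 39 features that rose in both, 35 had the larger difference in the deletion culture.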

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

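The tests of carried-over cells and of nitrogen exhaustion were chosen after the mating genes' values were seen, and so was the limit of 0.4 on the log2 scale used for opposite differences, while the tests of the intensity trend and of dim probe sets were set before their results. The ferroxidase gene fio1 stood out because the 2 mutant cultures lay on opposite sides of wild type, with log2 differences of 0.62 in the deletion culture and -0.47 in the adapted culture. Neither difference from wild type passed the size rule, while the fall of fio1 from the deletion to the adapted culture, 2.12-fold, did. Whether the cultures differed was not tested, as each had 1 array.

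Far more features were higher than lower in the deletion culture, 96.5% of those that passed the size rule. An intensity-dependent trend between arrays is argued against as the whole cause, because 95.6% were higher after its removal, 87 against 4. Noise of dim probe sets is argued against as well, since 98.1% were higher among features whose mean reached the table's median, 51 against 1. A response to the deletion stays open, and cannot be told apart from a peculiarity of these cultures with 1 array per group.

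M-type mating genes were higher in the adapted than in the deletion culture, with a list median of 0.99. Wild-type cells carried over from the plate are argued against, since 5 of 6 M-type genes lay above the wild-type array itself, which no mixture with cells at that level gives. The eca39 reading exceeded that of the deletion array by 0.0526% of the wild-type signal, a difference of 2 readings near background, and counted whole it would be 0.332%. A harvest nearer to nitrogen exhaustion should raise other nitrogen starvation genes too, whose median of -0.086 (1.79th percentile) without mei2 and ste11 speaks against it, but 5 lay above and 6 below 0, so it stays open. Adaptation and the earlier growth on a glutamate plate stay open and were not separated by the design.

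G1/S genes were lower in the deletion culture than in wild type, with a median of -0.42. Removal of the intensity trend left a median of -0.48, which argues against that trend as the cause. The criterion set beforehand also asked for every member below 0, and suc22 lay above 0 before and after the removal, so this part was relaxed, after the result was seen, to as many members below 0 as before, 6 of 7. A growth state of this 1 culture, such as a slightly different harvest density, may also give such a shift and cannot be told apart from an effect of the deletion with 1 array per group.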

How the results depend on the processing

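With 1 array per group no replicate could be left out, and no value has a replicate spread, so the standard deviation of all features' differences (0.1 for correlations) served as tolerance for values and a ratio of 1.5 for counts. Of 60 alternative counts 42 stayed within that ratio and 18 moved. Without the brightness limit, 148 features rose in the deletion and 124 in the adapted culture against wild type, and 18 rose and 28 fell between the mutant cultures. With the limit at the 50th percentile 4 rose between the mutant cultures, where mfm3, spk1 and ste7 were lost, as were mfm3, mmf2 and spk1 among the largest rises of the adapted and mmf2 among those of the deletion culture against wild type. With the limit at the 10th percentile, chosen after the data were seen, 87 rose in the adapted culture against wild type and 15 between the mutant cultures. At 1.5-fold, 197 rose and 22 fell in the deletion culture, 130 and 15 in the adapted culture, and 24 and 55 between the mutant cultures. At 3-fold, 36 rose in the deletion culture, 23 rose and 2 fell in the adapted culture, and 2 rose and 3 fell between the mutant cultures. These shifts follow from the construction of the limits and thresholds. The 3 other scalings kept the named genes with the largest differences past the size rule in all comparisons, and the share of higher calls in the deletion culture was 94.8% to 96.5%. Of 396 alternative list medians 395 moved less than the tolerance, which is wide for a median, so a median could change sign and still count as unmoved. Under repeated quantile normalization the meiosis list in the deletion culture did so, from 0.30 to -0.051. The meiosis list in the adapted culture moved beyond the tolerance, to 0.030, under the same setting, and the cause was not tested. Of 2730 alternative values for named genes 2698 stayed within it, and 16 of 16 for eca39 and the correlation did. Readings near background give no exact fold, so that of eca39 is a lower bound in both mutant cultures. No paired analysis was possible because each group had 1 array.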

Other observations

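The tests of chromosome ends below were prompted by where some of the highest genes lie, and the genes singled out here were chosen after their values were seen. Among named genes that rose in the deletion culture without being named by the fixed rule were gcn2, the gene of the kinase that senses uncharged tRNA (2.27-fold, 11.74 against 10.56 in wild type, 11.12 in the adapted culture), and arg4 (2.07-fold). The others were atm1, a mitochondrial transporter gene (2.46-fold), pdx1 (2.26-fold), car1 (2.24-fold) and egt1 (2.06-fold). Most features that rose had no name in the annotation used here, 55 of 82 in the deletion and 36 of 53 in the adapted culture, against 2082 of all 4981 features. The kinds of genes described above thus rest on the named minority of those that rose. The largest rise among them in both comparisons was probe set 1770944_at, which read 8.12 in wild type, 12.51 in the deletion and 11.74 in the adapted culture, followed by 1770946_at with 9.91, 13.87 and 13.47. The largest fall of an unnamed probe set against wild type was that of 1772389_at in the adapted culture, which read 12.96, 12.03 and 10.39 in the same order. Between the mutant cultures it was that of 1778377_at, which read 6.17, 9.84 and 6.99, the highest of these just above the brightness limit. Both, and 1 other unnamed probe set that went from 10.73 to 8.75, fell in that comparison by more than any named gene.

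The 4 probe sets named tlh2, a helicase gene next to a chromosome end, disagreed. In the adapted culture 1 of them read 9.82 against 5.87 in the deletion culture and 5.68 in wild type, and another read 8.24 against 5.14 and 5.34. The lower readings lay below those of the deleted eca39, so no fold is given. The remaining pair stayed near the bottom of the scale, at 4.47 in all cultures and at 3.90, 4.13 and 4.13. All values lay below the brightness limit, the highest of them only just, and such probe sets can also read the related genes at other chromosome ends.

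A hypothesis was that genes near the ends of chromosomes I and II were higher in the deletion culture because of their position. The 80 measured named genes nearest the 4 ends, 20 per end by gene order in assembly ASM294v3, had a median difference from wild type of 0.15, against 0 for the other named genes, with 57 above 0 and a percentile of 100 among matched random lists. They include the genes that prompted the test, and 62 that had been neither named nor called had one of 0.081 (99.62nd percentile), which that choice lowers by itself. In the adapted culture the same 62 had a median of 0.10 (98.6th percentile). Position is thus a candidate explanation for part of the differences, of a size not measured here, which 1 array per group cannot separate from the kinds of genes that lie there. Position may also lie behind the higher values of 2 tlh2 probe sets in the adapted than in the deletion culture. Between these cultures the 80 end genes had a median of -0.0058, at percentile 0.22, with 34 above and 40 below 0, isp5 at 1.11 and mug14 at -1.41 among them. The same 62 genes as above had a median of 0 (22.36th percentile), with 28 above 0, so the end genes did not rise as a set. The criterion set beforehand would exclude position at such percentiles. As single end genes went both ways, the set's median cannot decide whether position acted on tlh2 alone, so this stays open.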
